A study of Mus musculus with 6 samples.

How the data were processed

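RNA was sequenced from CT26 cells, a mouse colon carcinoma line, carrying either a control guide (sgControl, 3 libraries) or a guide against Cdk10 (sgCdk10, 3 libraries). Groups and replicate numbers were taken from the library titles. The authors deposited 1 table of counts per gene for all 6 libraries, with Ensembl gene identifiers and no normalization. The submitters' processing notes name HISAT2 2.2.1, featureCounts 2.0.3, DESeq2 1.40.2 and the build mm10, without saying which setting each was run with. The annotation release and the strand setting of the counting are not given in the sources used here. Reads from overlapping genes, antisense partners, paralogs and pseudogenes therefore cannot be separated with certainty, and a gene listed at 0 can be one whose reads were not assigned.

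The table held 57010 identifiers, of which 52029 had a symbol in GENCODE M21 and 4981 had none. Identifiers without a symbol held at most 0.284% of the counts of a library. Symbols are those of that release, so Ddx58 stands for Rigi, Tmem173 for Sting1 and Ero1l for Ero1a. Coordinates are from the same annotation on GRCm38. Totals lay between 17532202 and 19258309 counts per library. At this depth 3 counts, used as the floor of detection in a library, corresponded to 0.156 to 0.171 CPM. The floor covers counting error only.

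Genes were kept by edgeR's filterByExpr with a minimum count of 10 and a minimum total of 15, which left 13442 genes, 13242 of them with a symbol. Libraries were scaled by TMM factors. Differences were tested with edgeR 4.0.16, by the quasi-likelihood test with robust dispersion estimates and group as the only term, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. A positive log2 fold change means a higher level in sgCdk10. The standard error was derived from the fold change and its F statistic. CPM values are counts scaled to a common total by the TMM-adjusted library totals, and their SD is over 3 libraries. Nothing in the labels says that the libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

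The 23 gene lists, the tests and the rule for naming genes were fixed before the data were examined. A list with at least 3 tested members was tested with limma 3.58.1, by camera with a preset inter-gene correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were run as alternatives. The rule named Cdk10, the 12 largest rises and 12 largest falls among called genes with at least 1 CPM in the higher group, no overlap between the groups and a symbol that was not a predicted model, the 5 smallest p-values in each direction, the 4 members of each list with the smallest p, and 14 genes fixed in advance: Ifnb1, Cxcl10, Ccl5, Isg15, Ifit1, Rigi, Ifih1, Cgas, Sting1, Dnmt1, H2-K1, B2m, Cd274 and Ets2. Some genes that the rule names are not reported here. Genes outside this rule are marked where they appear as chosen after their values were seen.

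Alternatives fixed in advance were size factors of the DESeq2 type, DESeq2 1.42.0, limma-voom, no filter, a stricter filter of 1 CPM in every library of a group, non-robust dispersions, the replicate number as a block and leaving out each library in turn. A correction for GC content and transcript length, by a loess fit with a span of 0.5 used as offsets, was added after seeing the data. Of 4 further lists, those of HIF targets and interferon-stimulated genes outside the fixed lists were written before their members' values were looked at. Daxx, Tap1 and Lox, which also stood in fixed lists, were taken out of them after the values had been seen. The lists of immediate early and zinc-responsive genes were chosen after members had been seen.

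The scripts were tested on simulated counts for the sgCdk10 against sgControl comparison. These were drawn once from the real means, totals and dispersions of the 13442 genes, of which 13272 passed the filter in the draw. The edgeR test recovered 69.4% of 49 genes changed 1.25-fold, 70.8% of 48 changed 1.5-fold, 96.0% of 50 changed 2-fold and 93.8% of 48 changed 3-fold, each in the right direction. Of its calls, 8.38% were unchanged genes, above the nominal 5%. In the draw 13054 of the 13272 genes were unchanged, whereas 42.5% of the tested genes were called in the real data. The recovered and false shares depend on that fraction, so they do not carry over to the real data. A shift of 0.3 on the log2 scale in 1 list of 23 members was called by camera with adjusted p = 3.7e-27, and with adjusted p = 0.0109 with an estimated correlation, while 0 of the other 20 lists were called by either. Genes were drawn independently of each other, so this draw does not measure how often camera with the preset correlation calls a list of correlated genes by chance.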

Results

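Gene expression was measured by RNA sequencing in CT26 mouse colon carcinoma cells with a control guide or with a guide against Cdk10, the gene of cyclin-dependent kinase 10. Each group held 3 libraries. Total counts ran from 17532202 to 19258309, and 20989 to 21330 genes had at least 1 count. The title of the study ties Cdk10 to nucleic acid sensors and antitumor immunity, so the comparison asks which genes, and in particular which sensing and interferon genes, differed in the cells with the Cdk10 guide.

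Libraries of a group correlated more closely with each other (Pearson r over genes 0.994 to 0.996) than with the other group (0.987 to 0.990). The first principal component held 53.3% of the variance and separated the groups. The second, with 16.5%, set sgControl replicate 3 apart from the other 5 libraries. Pairs of replicates differed by more than sampling noise, with a chi-square per degree of freedom of 1.53 to 1.61, and of 4.30 and 4.36 for sgControl replicate 3 against replicates 1 and 2.

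Cdk10 mRNA fell in the cells with the Cdk10 guide. Its level was 20.4 ± 1.05 CPM in sgControl and 11.6 ± 1.24 in sgCdk10 (SD, n = 3), a log2 fold change of -0.82 (SE 0.08; edgeR adjusted p = 8.4e-09). Counts per library were 381, 344 and 365 in sgControl and 204, 227 and 202 in sgCdk10. Cdk10 (ENSMUSG00000033862) lies on chromosome 8, from 123224842 to 123232250 on the plus strand of GRCm38, with 8 merged exons. Its exons overlap those of the predicted gene Gm45842 and, on the opposite strand, of Spata2l, so part of the remaining count could not be assigned to Cdk10 with certainty. A count of mRNA does not measure the protein, and the guide's target site is not given in the labels. Among the 7 genes listed as CDK10 and its partners, Ets2, a transcription factor known as a substrate of the kinase, fell by 0.71 on the log2 scale (SE 0.04; edgeR adjusted p = 1.3e-13). Ets1 fell by 0.12 and the kinesin gene Kif5b rose by 0.12. In the whole list 1 gene rose and 4 fell, or 1 and 5 adjusted over the list alone, with camera adjusted p = 0.0186 and adjusted p = 0.105 with an estimated correlation. This list holds Cdk10 itself.

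Many genes differed, most of them by little. Of 13442 genes tested, 5717 (42.5%) were called by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2970 higher and 2747 lower in sgCdk10. Of these, 4938 changed by less than 1.5-fold and 201 by at least 2-fold, 131 higher and 70 lower; without a filter on low counts 333 genes passed that limit. Which direction held more calls depended on the setting: the GC and length correction, added after seeing the data, gave 2665 higher and 3222 lower, and leaving out sgControl replicate 3 gave 3023 higher and 3033 lower. The groups did not overlap in 51.3% of the tested genes, where chance gives 10%. The largest rises under the naming rule were those of Gem, Tmem95, Ankrd37, Kctd11, Bmp2, Acap1, Prdm1, Egr1, Hbegf, Egr2, Zbtb8b and Fosb, with log2 fold changes from 3.37 for Gem to 2.00 for Fosb. Gem and Tmem95 had at most 6 counts in any sgControl library, and without sgControl replicate 2 Gem had a log2 fold change of 4.08. Kctd11 rose from 6.39 ± 0.587 to 33.9 ± 1.55 CPM, and Egr1, an early growth response transcription factor, from 18.5 ± 0.881 to 86.0 ± 2.27 (SD, n = 3; edgeR adjusted p = 1.3e-20 for Egr1). Hbegf, a ligand of the EGF receptor, rose from 13.8 ± 1.87 to 58.2 ± 1.36 CPM. The smallest p-values among the rises also included Errfi1, a feedback inhibitor of the EGF receptor, at 1.54, Arhgap29 at 1.62 and Esm1 at 1.36 on the log2 scale. The largest falls were those of Adh1, Arl11, Amz1, Shtn1, Slc30a1, Mt2, Maats1, Arsg, Poln, Mmp28, Trib3 and Stard5, from -2.38 for Adh1 to -1.22 for Stard5. Adh1 had 18, 5 and 4 counts in the sgCdk10 libraries. Without sgCdk10 replicate 1 its log2 fold change was -3.37, so that library made the fall smaller and the size of the fall is uncertain. Slc30a1, a zinc exporter, fell from 32.8 ± 1.53 to 12.5 ± 1.24 CPM. Grem1, Mt1, Slc27a1 and Slc7a5 had, with Trib3, the smallest p-values among the falls, with log2 fold changes of -1.12, -0.86, -0.84 and -0.73. Exons of Ankrd37, Adh1, Amz1, Slc30a1, Mt2, Maats1, Arsg, Poln, Mmp28 and Stard5 overlap those of genes on the opposite strand, so their counts are less certain.

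**Figure D1:**
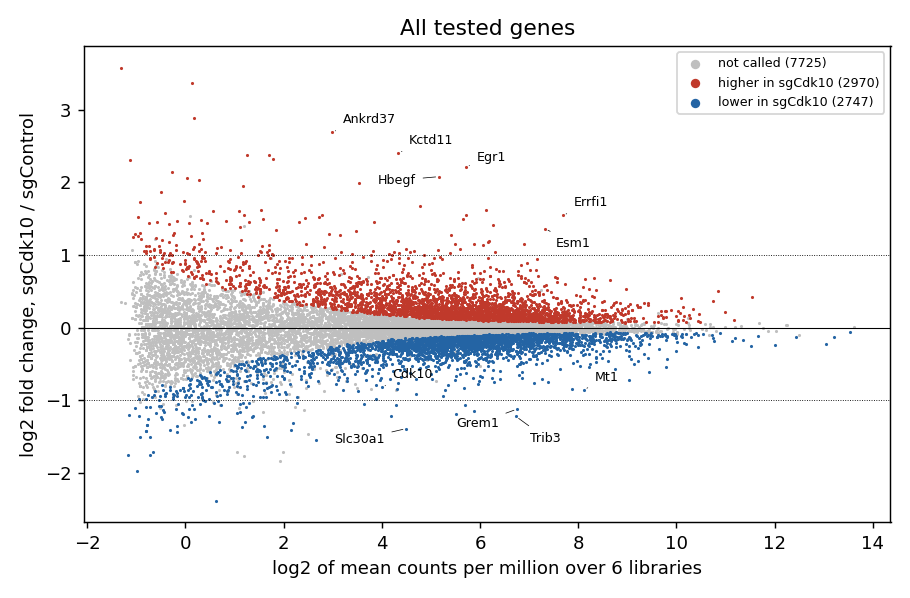
Each point is a tested gene, with the log2 of its mean CPM over the 6 libraries on the horizontal axis and its log2 fold change of sgCdk10 over sgControl on the vertical axis; dotted lines mark 2-fold changes. The 2970 red and 2747 blue genes passed the edgeR threshold, and most lie inside the dotted lines.

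Genes of nucleic acid sensing were higher in sgCdk10. Of 19 tested members of that list 13 rose and 2 fell (14 and 2 adjusted over the list alone), with a median of 1.26-fold and camera adjusted p = 7.5e-05. Ifih1, the gene of the RNA sensor MDA5, rose by 0.50 (SE 0.05) and Ticam1, an adaptor of Toll-like receptor 3, by 0.68 (SE 0.07) on the log2 scale. Ddx58, the gene of the RNA sensor RIG-I, rose by 0.25 and its ubiquitin ligase Trim25 by 0.36. Tmem173, the gene of STING, rose from 31.1 ± 0.919 to 41.6 ± 1.51 CPM (SD, n = 3), and Ifi204, a DNA sensor of the same pathway, by 0.43 on the log2 scale. Cgas, the enzyme upstream of STING, had 28.9 ± 1.67 CPM in sgControl and 28.6 ± 0.836 in sgCdk10 (edgeR adjusted p = 0.833). The 2 that fell, named after their values were seen, were Tbk1, by 0.19 (edgeR adjusted p = 0.000218), and Aim2, by 0.21 (edgeR adjusted p = 0.0134).

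Interferon-stimulated genes were higher as well, by small amounts. Of 35 tested, 24 rose and 1 fell, also when adjusted over the list alone, with a median of 1.20-fold and camera adjusted p = 6.5e-07. Oas2 rose by 0.71, Gbp7 by 0.65, Sp100 by 0.59 and Oasl2 by 0.32 on the log2 scale. Isg15 rose by 0.20 (SE 0.05; edgeR adjusted p = 0.00174). Ifit1 rose by 0.14 in edgeR (adjusted p = 0.0343), a call not made by DESeq2 (adjusted p = 0.154). None of the 35 tested genes was called with a change of at least 2-fold. The interferon gene Ifnb1 had 1, 1 and 1 counts in sgControl and 1, 2 and 2 in sgCdk10, under the floor of 3 counts, so no difference was detectable at this depth. Of the 8 tested interferon, cytokine and chemokine genes 2 rose and 0 fell, also adjusted over the list alone, with a median of 1.10-fold and camera adjusted p = 0.147. These were Lif, a cytokine of the interleukin-6 family, at 1.04 and Csf1, a macrophage growth factor, at 0.34 on the log2 scale. The chemokine Cxcl10 had a log2 fold change of 0.16 (edgeR adjusted p = 0.183), Ccl5 of -0.22 (edgeR adjusted p = 0.433) and Ccl2 of 0.19 (edgeR adjusted p = 0.392).

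Genes of antigen presentation and immune ligands rose in 9 of 22 tested cases and fell in 1 (10 and 1 adjusted over the list alone), with a median of 1.10-fold. Camera gave adjusted p = 0.0114, and adjusted p = 0.1003 with an estimated correlation. B2m, the light chain of class I molecules, rose from 479 ± 18.8 to 560 ± 14.9 CPM (SD, n = 3). H2-D1 rose by 0.14, Pvr by 0.17 and Tapbp by 0.17 on the log2 scale. H2-K1 rose by 0.09 in edgeR (adjusted p = 0.0406) with overlapping groups, and DESeq2 (adjusted p = 0.118), limma-voom (adjusted p = 0.0623) and edgeR with non-robust dispersions (adjusted p = 0.0597) did not call it. Class I genes have close paralogs, so reads may be divided between them. Cd274, the gene of PD-L1, had 2.91 ± 0.386 and 3.27 ± 0.463 CPM (edgeR adjusted p = 0.469). Of 16 NF-kB targets 9 rose and 3 fell, also adjusted over the list alone, with a median of 1.20-fold, camera adjusted p = 0.0124 and adjusted p = 0.0939 with an estimated correlation. Tnfaip3, a feedback inhibitor of the pathway, rose by 1.05, Vcam1 by 0.59, Ptgs2 by 0.30 and Nfkb2 by 0.22 on the log2 scale.

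Markers of leukocytes were low. Of 22 markers 2 were tested; Cd68, which also occurs outside macrophages, rose from 8.75 ± 0.206 to 13.0 ± 0.379 CPM, and Cd74 was not called (edgeR adjusted p = 0.519). The summed level of the 22 markers was 11.2 CPM in sgControl and 15.3 in sgCdk10, and without Cd68 2.50 and 2.31. Of 15 endothelial and adipose markers only Vwf was tested, and it was not called (edgeR adjusted p = 0.692).

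Targets of MAPK and ETS signalling had the highest median among the lists fixed in advance. Of 20 tested, 18 rose and 1 fell, also adjusted over the list alone, with a median of 1.39-fold and camera adjusted p = 9.7e-12. Besides Egr1, Dusp5 rose by 1.67, Fosl1 by 0.89 and Dusp6 by 0.71 on the log2 scale; Dusp5 and Dusp6 encode phosphatases of ERK. Of 21 genes of mesenchymal state and extracellular matrix 15 rose and 2 fell, also adjusted over the list alone, with a median of 1.19-fold and camera adjusted p = 5.5e-06. Snai1 rose by 0.95, Ccn1 by 0.79 and Fn1 by 0.37 on the log2 scale. Of 22 epithelial and colon genes 5 were tested, of which the keratins Krt18 (0.65) and Krt20 (0.51) rose and the mucin Muc2 fell by 0.93 from under 1 CPM (edgeR adjusted p = 0.0305), a call not made without a filter (adjusted p = 0.0630). Adjusted over the list alone the counts were also 2 and 1. Camera's direction for this list was up, with adjusted p = 0.459, while its median (-0.07) and mean (-0.05) were below 0.

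**Figure D2:**
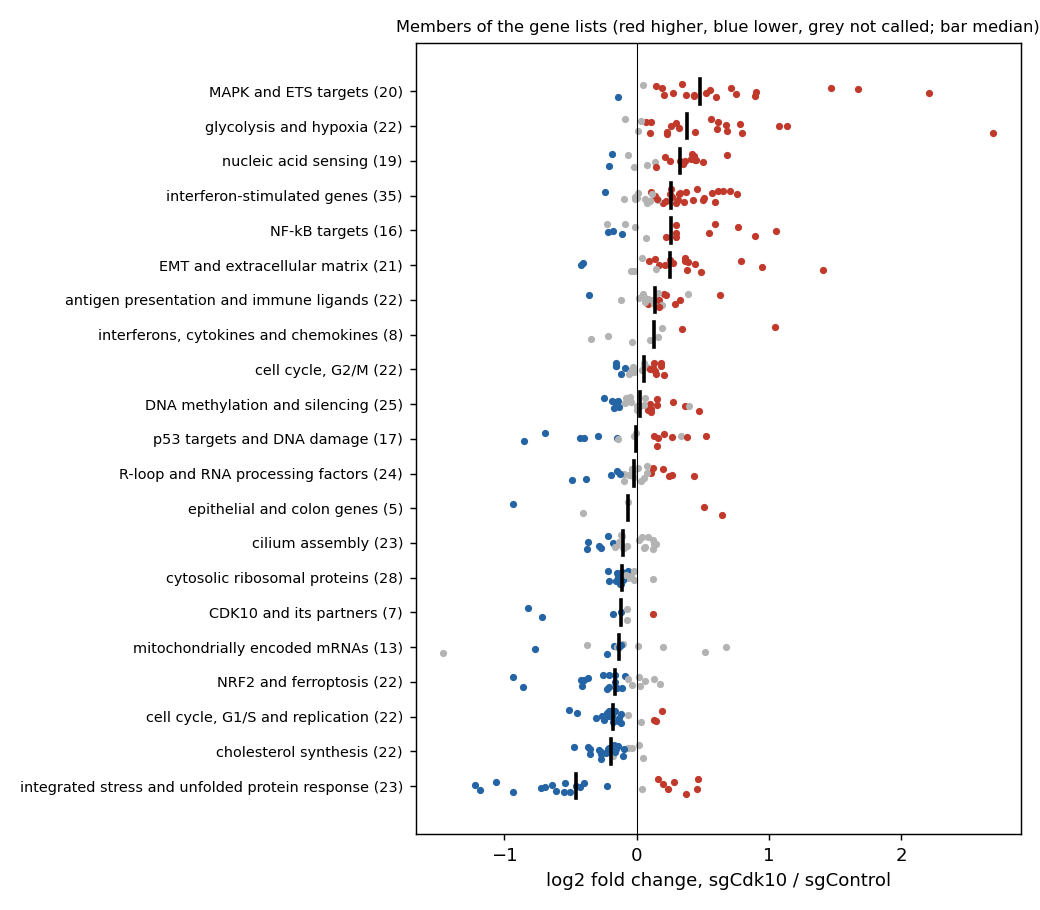
Each point is a tested member of a gene list, placed by its log2 fold change of sgCdk10 over sgControl on the horizontal axis, with the lists on the vertical axis sorted by median and the number of tested members in parentheses. Red and blue members passed the edgeR threshold; the medians run from -0.45 for the integrated stress and unfolded protein response to 0.48 for MAPK and ETS targets.

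Genes of glycolysis and hypoxia rose together. Of 22 tested, 19 rose and 0 fell, also adjusted over the list alone, with a median of 1.30-fold and camera adjusted p = 5.0e-14. Bnip3, a mitophagy receptor induced by hypoxia, rose from 41.5 ± 2.72 to 91.2 ± 4.29 CPM (SD, n = 3). P4ha1 rose by 0.80, Pdk1, a kinase that restrains pyruvate oxidation, by 0.78 and Ero1l by 0.67 on the log2 scale. Ankrd37, a known target of HIF, rose by 2.69 (SE 0.13).

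Genes of the integrated stress and unfolded protein response moved in both directions. Of 23 tested, 15 fell and 7 rose, also adjusted over the list alone, with a median of 0.730-fold and camera adjusted p = 5.5e-06. Trib3 fell from 148 ± 5.66 to 63.6 ± 0.440 CPM (SD, n = 3), Chac1 by 1.06, Slc7a5, an amino acid transporter, by 0.73 and Shmt2, an enzyme of serine metabolism, by 0.61 on the log2 scale. These are known targets of the transcription factor ATF4. The 7 that rose, named after their values were seen, were Hspa5, Hsp90b1, Pdia4, Creld2, Sdf2l1, Xbp1 and Edem1, which act in folding or clearance of proteins in the endoplasmic reticulum or, for Xbp1, regulate it, and their log2 fold changes ran from 0.16 to 0.46.

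Genes of cholesterol synthesis were lower. Of 22 tested, 17 fell and 0 rose, also adjusted over the list alone, with a median of 0.876-fold and camera adjusted p = 6.5e-07. Insig1 fell by 0.47, Lss by 0.35, Hmgcs1 by 0.35 and Nsdhl by 0.27 on the log2 scale. Of 22 genes of the NRF2 and ferroptosis list 15 fell and 0 rose, also adjusted over the list alone, with a median of 0.894-fold and camera adjusted p = 1.7e-05. Slc7a11, the cystine transporter, fell by 0.94, and the glutathione synthesis genes Gclc and Gclm fell by 0.42 and 0.39 on the log2 scale. Slc7a11 is also a member of the stress response list.

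Genes of the G1/S transition and DNA replication were lower. Of 22 tested, 17 fell and 3 rose, also adjusted over the list alone, with a median of 0.886-fold and camera adjusted p = 5.5e-06. Tk1 fell from 131 ± 2.87 to 92.5 ± 1.28 CPM (SD, n = 3), Pole by 0.45, Mcm6 by 0.31 and Rrm2 by 0.24 on the log2 scale. Of 22 genes of the G2/M phase 8 rose and 5 fell (10 and 5 adjusted over the list alone), with a median of 1.04-fold and camera adjusted p = 0.296. Kif20a rose by 0.19 and Ube2c fell by 0.16 on the log2 scale. Of 17 p53 targets 7 rose and 6 fell, also adjusted over the list alone, with camera adjusted p = 0.942. Cdkn1a, the inhibitor p21, rose by 0.52 and Gadd45a fell by 0.85 on the log2 scale. Camera's direction was up for this list while its mean was -0.05.

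Of 25 genes of DNA methylation and silencing 9 rose and 6 fell (10 and 7 adjusted over the list alone), with camera adjusted p = 0.848. Dnmt1, the maintenance methyltransferase, fell from 423 ± 8.14 to 377 ± 3.40 CPM (SD, n = 3; edgeR adjusted p = 2.2e-05). Dnmt3a, a de novo methyltransferase, rose by 0.37 and Tet2, which oxidises methylcytosine, by 0.47 on the log2 scale. Of 24 R-loop and RNA processing factors 6 rose and 5 fell (7 and 5 adjusted over the list alone), with camera adjusted p = 0.884. Cdk12 rose by 0.43 and Rnaseh2b, a subunit of ribonuclease H2, fell by 0.48 on the log2 scale. Of 23 cilium assembly genes 6 fell and 0 rose (4 and 0 adjusted over the list alone), with camera adjusted p = 0.178; Bbs7 fell by 0.37 and Ift172 by 0.28.

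Ribosomal protein genes were slightly lower. Of 28 tested, 20 fell and 0 rose, also adjusted over the list alone, with a median of 0.928-fold, camera adjusted p = 1.8e-06 and adjusted p = 0.169 with an estimated correlation. With the GC and length correction, added after seeing the data, camera gave adjusted p = 0.0241 for this list. Rpl30 fell by 0.21 on the log2 scale. These genes have many processed pseudogenes that can share their reads. Of 13 mitochondrially encoded mRNAs 5 fell and 0 rose (3 and 0 adjusted over the list alone), with camera adjusted p = 0.0494 and adjusted p = 0.398 with an estimated correlation. Without sgControl replicate 3, in which mitochondrial genes held 4.93% of the counts against 4.19 to 4.40% in the other 5 libraries, camera gave adjusted p = 0.0650, and without sgCdk10 replicate 1 or 2 adjusted p = 0.106 or 0.0749. The lists called with the preset correlation and also with an estimated one were 9 of 14: nucleic acid sensing, interferon-stimulated genes, MAPK and ETS targets, mesenchymal state and extracellular matrix, glycolysis and hypoxia, stress response, cholesterol synthesis, NRF2 and ferroptosis, and G1/S genes, with adjusted p from 0.0382 to 0.0387.

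**Figure D3:**
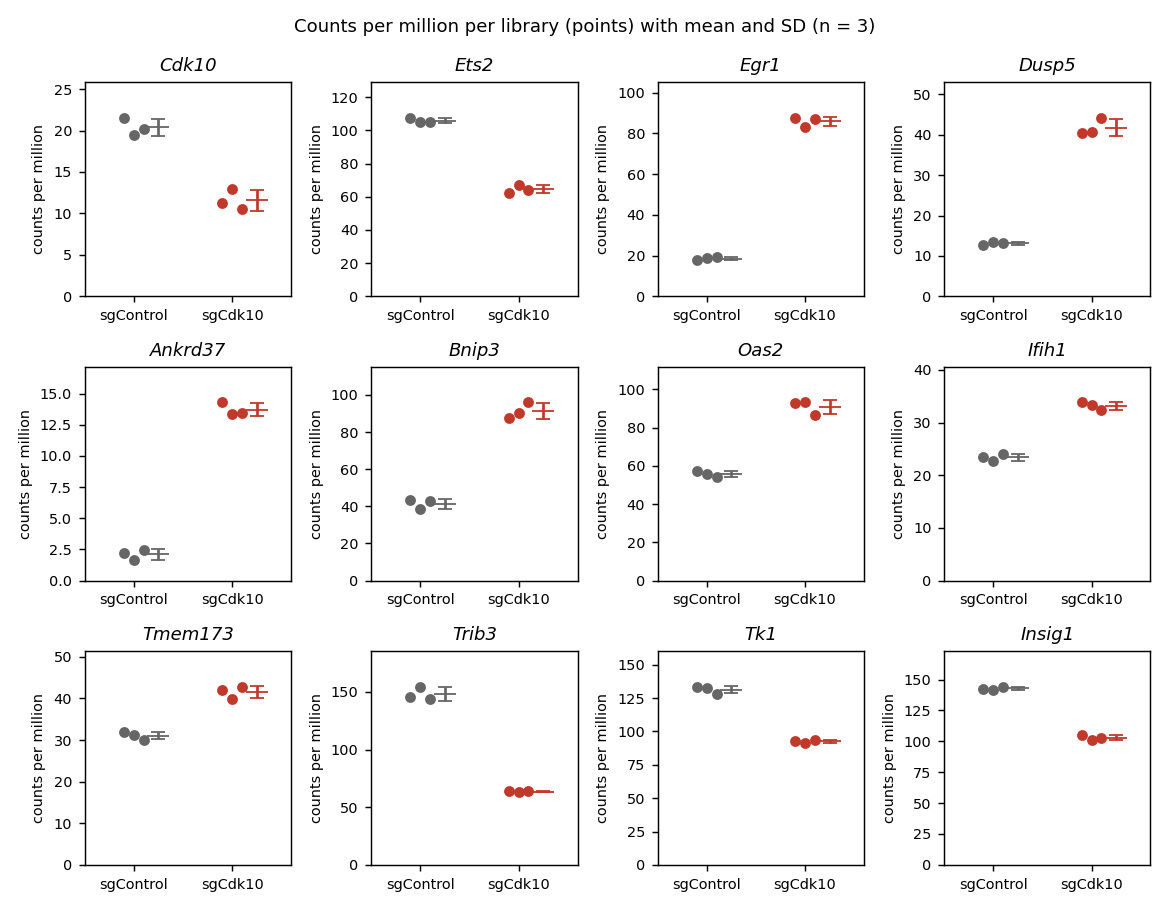
CPM of 12 named genes in each library (points), with the group mean and SD beside them (n = 3), for sgControl in grey and sgCdk10 in red; each vertical axis starts at 0. The groups do not overlap in any of the 12 genes, and Cdk10, Ets2, Trib3, Tk1 and Insig1 are lower in sgCdk10.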

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

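Alternatives were fixed before the data were examined, except the GC and length correction, which was chosen after seeing the data. With all 6 libraries the count of changed genes ranged from 4179 with DESeq2 to 5887 with the GC and length correction, against 5717. Leaving out 1 library gave 4791 to 6056 calls, and 81.6 to 92.4% of the 5717 were called again in the same direction. The count of genes changed at least 2-fold was 201, rose to 333 without a filter, where 27130 genes were tested, and was 217 to 280 with a library left out. Cdk10 stayed lower in every alternative run, with log2 fold changes from -0.90 to -0.75. The replicate block gave 5481 changed genes and 207 changed at least 2-fold, a Cdk10 log2 fold change of -0.82, moved no list across the threshold, and among the named genes ended the call of H2-K1 alone (adjusted p = 0.0532). Leaving the replicate number out of the main fit was fixed in advance. Same-numbered libraries correlated in their deviations from the group means at 0.08, -0.09 and -0.10, and not every library correlated best with its own number. Deviations from a mean of 3 libraries are tied to each other, so these values can neither show nor exclude pairing. With an estimated correlation 5 lists were no longer called: CDK10 partners (0.105), antigen presentation (0.1003), NF-kB targets (0.0939), mitochondrial mRNAs (0.398) and ribosomal proteins (0.169). The estimated correlations of these lists were, in the same order, -0.15, 0.0109, -0.029, 0.22 and 0.24, against the preset 0.01. A higher correlation therefore does not account for the lost calls of CDK10 partners and NF-kB targets, and hardly for that of antigen presentation. Fry, which does not compare a list with other genes, also called cytokines (0.00215), G2/M (0.0105), epithelial genes (0.0105) and cilium genes (0.00379). It did not call mitochondrial mRNAs (0.135), and turned the direction of the uncalled p53 (0.134) and R-loop (0.942) lists. Mitochondrial mRNAs also missed the threshold with the stricter filter (0.0607) and the GC and length correction (0.142), with 0.00614 to 0.106 when a library was left out. The p53 list, never called by camera, turned direction in 2 of those fits, with 0.852 to 0.983, and the GC and length correction turned that of the DNA methylation list (0.481). Among the named genes, 962 values under other settings matched the main call and 8 missed the threshold; with a library left out 709 matched, 19 missed it and 4 turned direction. Those 4, none of them called, were Ccl2 (-0.00425 to 0.31), Vwf (-0.32 to 0.11), Ccl5 (-0.41 to 0.0277) and Cgas (-0.0450 to 0.0306). Calls lost, by adjusted p, were Muc2 without sgControl replicate 2 or 3 or any 1 sgCdk10 library (0.0606 to 0.0963), Ifit1 without sgControl replicate 1 or 2 or sgCdk10 replicate 3 (0.0736 to 0.190), H2-K1 without sgControl replicate 1 or 2 or sgCdk10 replicate 1 or 3 (0.0566 to 0.205), mt-Nd3 without sgControl replicate 3 (0.0749), and mt-Cytb and mt-Nd4 without any 1 sgCdk10 library (0.0559 to 0.0838). The cause of these changes was not tested, except that fewer libraries or more tested genes follow from the settings themselves. Depth limits genes at a few counts, such as Ifnb1.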

Other observations

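The tests of leukocyte RNA, of GC content and length on single lists, and of the lists of interferon-stimulated genes and HIF targets outside the fixed lists were set down only after the results they measure had been seen, and the GC and length correction was itself chosen after seeing the data. Junb, Egr3, Jun, Fosl2, Klf4, Klf6, Myc, Slc39a10, Bst2, Lyz2, Tyrobp, Fcer1g, Stc2 and Vldlr were chosen for naming after their values were seen.

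Immediate early genes were listed after Egr1, Egr2 and Fosb had been seen among the largest rises, and the list shares Egr1, Fos, Fosl1, Ier3 and Myc with the MAPK list, so its counts are a description and no set test is given. Of 22 tested, 14 rose and 2 fell (15 and 2 adjusted over the list alone), 8 of the rises being at least 2-fold, with a median of 1.51-fold. Junb rose by 1.55, Egr3 by 1.52, Jun by 1.15 and Fosl2 by 1.14 on the log2 scale, while Klf4 and Klf6 fell by 0.39 and 0.20, and Myc had 0.05 (edgeR adjusted p = 0.427). Zinc-responsive genes were listed after Mt1, Mt2 and Slc30a1 had been seen, and are also only described. The metallothioneins Mt1 and Mt2 and the exporter Slc30a1 fell by 0.86, 1.37 and 1.39, and the zinc importer Slc39a10 rose by 1.28 (edgeR adjusted p = 9.8e-16). These were the 4 tested members.

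The first pattern is the breadth of the change. In the 10 splits of the 6 libraries into 3 and 3, the real one included, 1 gave as many as 5717 genes and 1 as many as 201 genes changed at least 2-fold, the highest of the others being 0 for both in edgeR, with 104 to 238 genes at an unadjusted p under 0.05 against 6670; mixed splits put the group difference into the spread, and 10 splits are too few for a share under 0.05. For lists called by camera with the preset correlation 1 split gave as many as 14. Each of the others gave 6 to 9 although 0 genes were called in them, so this test can call a list without any gene call. With an estimated correlation 1 split gave as many as 9 lists, and the highest of the others was 0. Each mixed split keeps part of the group difference between its sides, so its list calls may be real shifts at reduced size. The difference put into the spread may also raise the estimated correlation, whose values in these splits were not looked at. Neither count therefore measures how often camera calls a list falsely. Without sgControl replicate 3, which stands apart, 92.4% of the calls were made again in the same direction, and after the GC and length correction 87.6%, which argues against either as the whole source. The spread within groups was small, with a common coefficient of variation beyond sampling of 3.12% in edgeR, so small differences could be called. What stays open is whether the libraries of a group are separate cultures or cell pools, which the labels do not say. A spread this small may be technical.

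The second pattern is the rise of interferon-stimulated genes. RNA of leukocytes in the sgCdk10 cultures is argued against by the markers: their sum rose by 4.08 CPM, and by -0.19 without Cd68, which a first form of the test had left out, against a rise of 52.3 for Bst2, the largest single one in the list, and Lyz2, Tyrobp and Fcer1g had at most 4 counts summed over a group. Bst2 was picked as the largest rise in the same data, and its log2 fold change of 0.57 had an SE of 0.10. Other members rose by less, Isg15 for example from 37.2 to 42.8 CPM. For such small rises the comparison with Bst2 does not decide, and only the sum without Cd68, which did not rise, argues against leukocytes. After the GC and length correction the median log2 fold change of the interferon-stimulated list was 107% of the uncorrected one. Interferon-stimulated genes outside the fixed lists had a median of 0.24, with 23 of 32 higher and 1 lower. Camera gave adjusted p = 2.1e-07 with the preset correlation and adjusted p = 0.0461 with an estimated one. These values were adjusted over all 4 added lists, including the immediate early and zinc lists chosen after members had been seen. The rise may thus extend to a broader interferon programme. No interferon gene of the fixed list had enough counts to be tested, and culture differences between the groups stay open.

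The third pattern is the rise of hypoxia and glycolysis genes. HIF targets outside the fixed list had a median of 0.43, with 16 of 22 higher and 2 lower. Camera gave adjusted p = 2.3e-09 with the preset correlation and adjusted p = 0.0461 with an estimated one, adjusted over the same 4 added lists. The rise may thus extend to the wider HIF programme. The 2 that fell were Stc2, a target also driven by ATF4, by 0.55 and Vldlr by 0.12. After the GC and length correction the median of the fixed list was 92.6% of the uncorrected one. A difference in culture density, oxygen or medium between the groups cannot be told apart from an effect of the guide, because 0 libraries carry a label of density, medium or harvest. The same limit holds for all other differences between the groups. These include the MAPK and ETS, immediate early, stress response, cholesterol, zinc-responsive and G1/S genes.

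Among tested genes with a mean log2 CPM above 3, 22 of 184 processed pseudogenes were in sgControl replicate 3 at least 1.5-fold above the mean log2 CPM of sgControl replicates 1 and 2 and 1 was as far below, against 4 and 3 of 9018 protein-coding genes. Between replicates 1 and 2, 0.544% of these pseudogenes were at least 1.5-fold apart. Within 500 kb of Cdk10, 21 other genes were tested, of which 8 fell and 0 rose, with a median log2 fold change of -0.14. Of all tested genes 42.5% were called, 2970 higher and 2747 lower. The medians of whole chromosomes lay between -0.03 and 0.02, but these hold 347 to 1046 genes and so vary less. Windows of similar size were not compared, so no effect of the region can be read from this. Across genes, the log2 fold change had a Spearman rho of 0.19 with transcript length and of 0.03 with GC content, and genes are not independent replicates.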
